A study of Mus musculus with 17 samples.

How the data were processed

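The series holds single-cell CUT&Tag libraries, in which an antibody against a chromatin protein or mark guides a transposase that cuts and tags the DNA beside it inside single nuclei. It lists 17 samples: 15 from mouse brain and 2 from a mixture of 3 mouse cell lines, both profiled for H3K27me3, the histone mark left by the Polycomb repressive complexes. The lines are 3T3 (embryonic fibroblasts), mESC (embryonic stem cells) and Oli-neu (an immortalised oligodendrocyte precursor line). Only the mixture came with a data file, so the 15 brain samples are not analysed here. The file names 2 libraries, called library 1 and library 2 below. The labels call the mixture samples v1 and v1.1, and nothing in the file says which library is which version, so no version is attached to a value. Nothing says that the 2 libraries came from separate cultures of the lines, so the spread between them, and every p-value built on it, may be technical.

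The authors deposited a list of fragments, each with a cell barcode and the count of read pairs behind it. The start and end position of each fragment in the deposited list are genome coordinates, with no signal value of their own. Reads were aligned and fragments made with Cell Ranger ATAC 1.2.0 on the mm10 genome, and analysed further with Seurat and Signac, per the submitters' processing notes. How the libraries were merged into 1 list is not stated in the labels. Here each fragment was counted once, at its midpoint. The number of per-sample value columns belonging to no sample was 0. The 2 libraries hold 4687053 and 4090142 fragments, read with 104897203 and 130933158 read pairs.

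A barcode was taken as a cell when it held at least 188 fragments. This number is the lowest point between background and cells in the histogram of log10 fragments per barcode (steps of 0.05, Gaussian smoothing over 2 steps), where the mode of the cells lies at 473. Cells of both libraries were clustered together: presence of a fragment in bins of 50 kb seen in at least 20 cells, term frequency and inverse document frequency, singular value decomposition, 11 components after leaving out the first, a graph of 20 nearest neighbours weighted by shared neighbours, and Leiden clusters at a resolution of 0.1. A gene in use in a line should lack H3K27me3 there, so a cluster was called mESC-like, 3T3-like or Oli-neu-like when the 15 markers fixed for that line had the lowest level there, with a median log2 deviation from the mean over all clusters under -0.5 (pseudocount of 5 CPM). Other clusters stay unnamed. The class names rest on H3K27me3 fragments alone, since the file holds no other label of a cell's line. Barcodes holding nuclei of more than 1 cell were not removed from the main analysis. To keep the clustering from choosing the tested genes, cells were classified 2 times: from odd-numbered autosomes for the genes on even-numbered autosomes and X, and from even-numbered autosomes for the others.

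Genes were the 21631 protein-coding genes of the GRCm38.p6 (mm10) annotation outside chromosome Y. The plan was a window of 5 kb either side of the gene start. The annotation given carries no strand, so the window was set to 5 kb either side of both gene ends, which makes the windows of neighbouring genes overlap. Fragments were summed per gene, class and library, which gave 526206 to 1872764 fragments per class and library. The test was edgeR 4.0.16 (quasi-likelihood fit and test, TMM scaling, filterByExpr) in R 4.3.3, with the class and the library as terms. One fit held all 3 classes of both libraries, with 2 residual degrees of freedom. Each contrast sets a class against the mean of the other 2 on the log2 scale, with Benjamini-Hochberg adjustment and a threshold of 0.05. Values per gene are CPM of fragments after TMM scaling, pooled over both libraries. Tested on simulated data with 50 genes changed at each size, the test recovered 46 to 82% of 2-fold rises and 94 to 100% of 4-fold rises, with 28 to 54% and 56 to 78% of falls of the same sizes, and 3 to 9 false calls per contrast. Only these genes were changed among the 9898 of the simulation. The data gave 6023 to 7576 calls per contrast, so these rates may not carry over to them.

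Gene lists were tested with camera (limma 3.58.1, inter-gene correlation of 0.01, and again with an estimated correlation) and with fry, adjusted over the lists of each contrast. With an estimated correlation camera rests on the 2 residual degrees of freedom of the fit, so it can hardly call a list or family here. A call lost in that form is therefore not evidence against the list. The lists were the 4 Hox clusters, neural patterning factors, neuronal differentiation factors, astrocyte and radial glia genes, endoderm factors, mesoderm and muscle factors, blood and immune factors, Wnt and BMP ligands, cell cycle inhibitors, imprinted genes, germline genes and housekeeping genes. No housekeeping gene passed the filter on low counts, so that list has levels and no test. The named genes of a contrast are the 10 largest rises and the 10 largest falls by fitted value among genes that pass the threshold, are not markers, and differ the same way from each of the other classes in both libraries, plus the 2 members of each list with the largest absolute change, and not every gene this rule picks is printed. Other genes named from a list are given as examples chosen after their values were seen. The markers, lists, tests, named-gene rule and most alternatives were fixed before the data were examined, and the alternatives added later are named as such in the closing section.

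Where a class has no fragment at a gene, a fold is a lower bound computed against a floor of 3 fragments over both libraries of that class. With 1 to 3 fragments the ratio is given with its exact 95% counting interval. Shares carry exact binomial (Clopper-Pearson) intervals at 95% and levels exact Poisson intervals. All intervals and floors cover counting error only. The concentration of the mark is the share of a class's fragments in the 5% of 10 kb windows highest in that class, with windows chosen on a random part of the cells and read in the rest. Alternatives were DESeq2 1.42.0, scaling by total fragments or by totals per chromosome, no filter on low counts, windows of 2.5 kb or the whole gene plus 2 kb either side, classes from all autosomes, no library term, other cell minimums (94 and 376), thinning to 526206 fragments per class and library, leaving out the 150 cells whose odd-numbered and even-numbered autosomes gave different classes, leaving out each library, clustering on 5 kb bins, and k-means with 3 clusters on 5 components. With 1 library left out, a change is the difference of log2(CPM + 1), with no test. Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, python-igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.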

Results

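The H3K27me3 mixture gave 10101 cells, 5540 in library 1 and 4561 in library 2, with 7749133 fragments between them. Some of these barcodes may not be separate cells. The count was 9613 without copies between libraries and 9025 with at least 5 read pairs per fragment, alternatives chosen after the data were seen. The median cell held 521 fragments in library 1 (quartiles 333 and 850) and 525 in library 2 (quartiles 333 and 877). Cells took 88.9% and 87.5% of the fragments of the libraries, and 115620 barcodes lay under the minimum of 188 fragments. The comparison implied by the design is between the lines of the mixture: whether H3K27me3 fragments separate them, and which genes carry the mark in each. The 2 libraries are the replicates of every value below. Fragments with the same ends and barcode in both made 14.7% of library 1 and 16.9% of library 2. The main fit kept them, so the libraries are not fully independent, and the spread behind the p-values may be understated. Without the copies that had fewer read pairs, an alternative chosen after the data were seen, 7373, 5672 and 6170 genes differed in mESC-like, 3T3-like and Oli-neu-like cells.

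**Figure D1:**
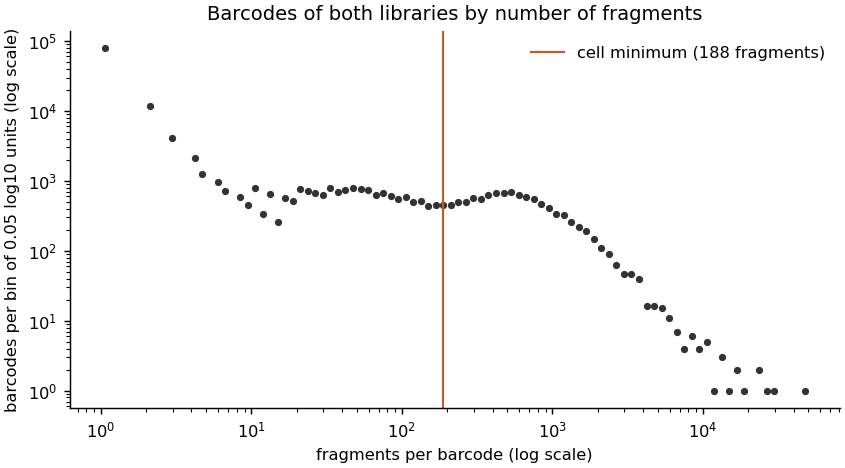
Number of barcodes of both libraries (vertical axis, log scale, bins of 0.05 log10 units) by fragments per barcode (horizontal axis, log scale). Each point is a bin, and the line marks the cell minimum of 188 fragments, in a shallow valley left of the mode of the cells at 473.

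H3K27me3 fragments alone split the mixture into 3 line-like classes and a small group that matched none. Where fragments fall can reflect the chromosome copies of a line as well as the mark. Neither the split nor the agreement of autosome sets below can thus be credited to the mark alone. Oli-neu-like cells made up 39.2% of all cells (3961 cells, 95% interval 38.3 to 40.2), mESC-like cells 35.1% (3544 cells) and 3T3-like cells 18.9% (1910 cells, 18.1 to 19.7). The remaining 686 cells (6.79%, 6.31 to 7.30) had no line's markers low and stay unnamed. The shares of library 1 and library 2 were 40.2% and 38.0% for Oli-neu-like, 35.1% and 35.1% for mESC-like, 19.9% and 17.7% for 3T3-like, and 4.82% and 9.19% for unnamed cells. Cells classified separately on odd-numbered and even-numbered autosomes received the same class in 98.5% of cases (9951 of 10101 cells, 98.3 to 98.7), with 98.7% in library 1 and 98.3% in library 2. The shares depended on the settings: at a minimum of 94 fragments mESC-like cells made 22.8% and unnamed cells 21.8%, at 376 unnamed cells made 3.55%, and k-means with 3 clusters gave 28.7% 3T3-like cells. At 94 a cluster of 1709 cells stayed unnamed, with median log2 deviations of 0.82 at 3T3, 0.59 at Oli-neu and -0.12 at mESC markers. Even-numbered autosomes alone gave 4624 mESC-like and 1138 unnamed cells there. The 22.8% thus depends on how clusters split and miss the naming threshold. Of the alternatives chosen after the data were seen, a finer clustering at a resolution of 0.4 gave 18.8% mESC-like cells, and with at least 5 read pairs per fragment no cell was unnamed. At 0.4, clusters of 872 and 850 cells drawn mostly from mESC-like cells missed the naming threshold.

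Each class lacked the mark at most markers of its own line. In mESC-like cells, 9 of the 12 measured mESC markers were lower than in the other classes, led by Sall4 (3.75 CPM against 53.4 in 3T3-like and 19.7 in Oli-neu-like cells) and Nanog (2.60 against 50.7 and 8.87), both pluripotency factors. Klf4 and Prdm14, also mESC markers, went the other way, with Klf4 at 134.2 against 0.921 and 8.87. In 3T3-like cells, 10 of 13 measured fibroblast markers were lower, among them Twist1 (1.84 against 135.9 in mESC-like cells) and Col1a2, a collagen chain with no fragment in 3T3-like cells, at least 14.6-fold lower than in mESC-like and at least 10.8-fold lower than in Oli-neu-like cells. Postn, another fibroblast marker, was higher there (13.8 against 2.31 and 2.30). In Oli-neu-like cells, 10 of 13 measured oligodendrocyte lineage markers were lower, among them Olig1 (5.91 against 86.0 and 45.1) and Sox10 (12.8 against 118.0 and 146.4), while Lhfpl3 was higher (402.5 against 122.4 and 30.4). The counts adjusted over the list alone were the same for these 3 lists in their own class. In mESC-like cells the log2 fold change of Nanog was -2.27 without library 1, and that of Sall4 moved from -3.08 to -2.46 without library 2. These markers named the classes, so their direction there is not independent evidence.

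**Figure D2:**
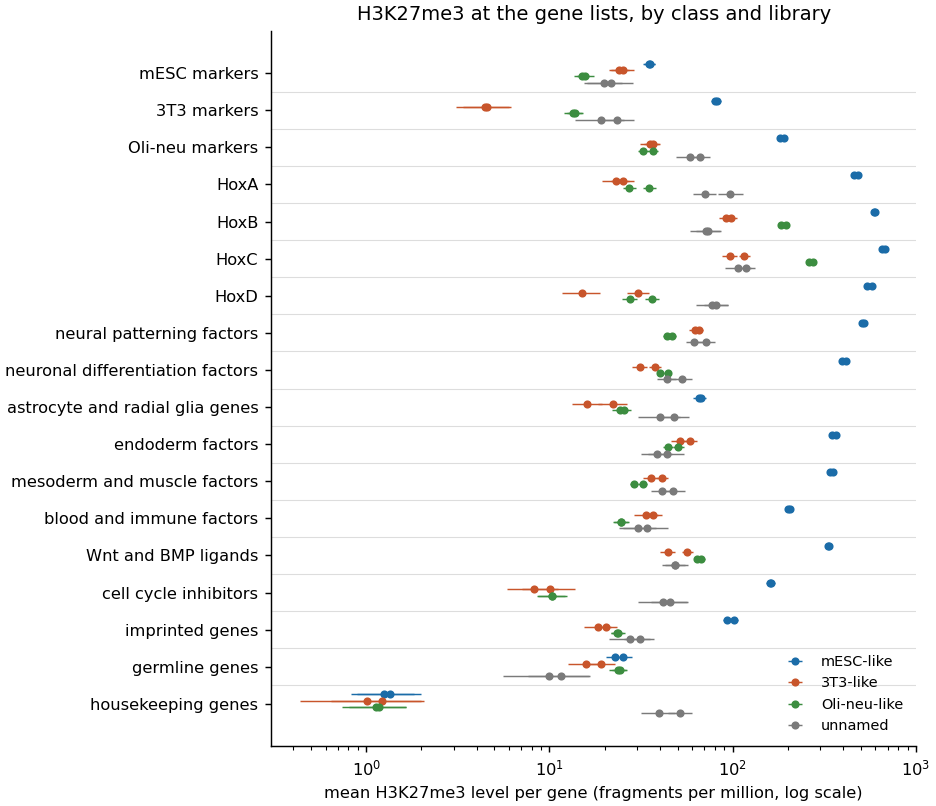
Mean H3K27me3 level per gene (CPM over all fragments, log scale) at the 3 marker lists and the 15 gene lists, for each class. Each point is a library and each bar its exact 95% counting interval. The mean of the mESC markers is highest in mESC-like cells because of a few members, where their median is lowest, and the housekeeping genes reach 47.0 in unnamed cells against 1.13 to 1.30 in the named classes.

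H3K27me3 was more concentrated in mESC-like cells than in the other lines. The 5% highest 10 kb windows held 63.6% of the fragments of mESC-like cells, 48.3% in 3T3-like, 47.6% in Oli-neu-like and 31.8% in unnamed cells. The libraries gave 64.8% and 62.3% for mESC-like, 48.7% and 47.8% for 3T3-like, 48.0% and 47.2% for Oli-neu-like and 27.8% and 33.9% for unnamed cells, so the gap of mESC-like cells to the other lines was larger than the spread between libraries. 3T3-like cells stood slightly above Oli-neu-like cells within each library, and after thinning to equal fragments the libraries gave 48.4% and 47.5% against 47.0% and 46.1%. With windows chosen over all 3 classes together, a choice made after the data were seen, the order of these classes turned, at 34.9% in 3T3-like and 43.3% in Oli-neu-like cells.

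The classes also differed in how fragments fell on chromosomes, a measure of chromosome copies and of the mark at once. Chromosome X took 2.18% of fragments in mESC-like cells against a mean of 1.40% in the other classes, and 1.25% in Oli-neu-like cells against 1.86%. Chromosome 3 took 5.55% in 3T3-like cells against 3.94%, and chromosome 14 took 2.32% against 3.23%. Chromosome 15 took 6.67% in Oli-neu-like cells against 4.91%, and 4.57% in mESC-like cells against 5.96%. Library 1 and library 2 gave 2.18% and 2.18% for chromosome X in mESC-like cells, 5.56% and 5.52% for chromosome 3 in 3T3-like cells, and 6.67% and 6.67% for chromosome 15 in Oli-neu-like cells. All 6 kept their direction without the highest windows.

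mESC-like cells against the other classes: the developmental regulators carried the mark in mESC-like cells. All 11 genes of HoxA and all 9 of HoxD, the clusters that set position along the body axis, were higher, with a median log2 fold change of 3.84 and 3.86, and so were all 10 of HoxB (1.76) and all 9 of HoxC (1.61). All 26 neural patterning factors rose (median 3.19), as did 26 of 28 neuronal differentiation factors (3.37) and 20 of 22 mesoderm and muscle factors (3.16, and 2.98 with genes at 0 in a class set to their bound). Krtap31-1, a keratin-associated protein gene, and the C-type lectin genes Clec2h and Clec2f were among the largest falls.

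Within the Hox clusters, Hoxa4 (Entrez 15401, chromosome 6, 52189682 to 52191703) stood at 167.4 CPM in mESC-like cells against 4.61 in 3T3-like and 10.8 in Oli-neu-like cells, a log2 fold change of 4.54 ± 0.22 (SE from the fit of 2 libraries). Here and below, this SE is the size of the fitted change divided by the square root of its F statistic. Hoxa2 changed by 4.26, Hoxd4 by 4.31 and Hoxd3 by 4.05, while Hoxb5 and Hoxb3 changed by 2.25 and 2.23, Hoxc12 by 2.36 and Hoxc6 by 1.78. Among neural patterning factors Irx5 reached 381.2 against 18.4 and 26.9 (4.09 ± 0.16). Among neuronal factors Dlx1 changed by 4.18 and Phox2a by 4.01. Of the endoderm factors 10 of 12 rose, with Gata6 at 4.25 and Gsc at 4.08, while Hnf4a and Foxa3 fell. Of the mesoderm and muscle factors Tbx5 fell and Meox1 did not pass. Myf6 and Myf5, the pair with the largest fitted changes in that list, had no fragment in 3T3-like cells: Myf6 was at least 5.01-fold higher in mESC-like than in 3T3-like cells and Myf5 at least 2.92-fold. Their fitted log2 changes of 4.60 and 4.32 were 2.76 and 2.68 without library 1, and 2.91 and 2.39 without library 2, where 1 is added to each CPM value and changes at genes near 0 shrink by construction.

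Wnt and BMP ligands, secreted signals of development, rose in 20 of 21 cases (median 2.41), with Gdf7 at 3.92 and Bmp4 at 3.55. Of the blood and immune factors 6 of 9 rose and 2 fell (Gata1 and Spi1), led by Lyl1 (4.62) and Gata2 (3.85). Of the cell cycle inhibitors 6 of 7 rose, led by Cdkn2c (4.45) and Cdkn2a (4.31), which encodes p16 and Arf, and Cdkn2d fell (-2.06). Imprinted genes, expressed from 1 parental copy, rose in 12 of 14 cases, with Igf2 at 3.17 and Phlda2 at 2.57, and fell in 2. The astrocyte and radial glia genes went both ways, with 3 of 8 higher, Hes5 and Sox9 (both 2.86) among them, and 2 lower. The germline genes did so too, with 2 of 9 higher, Slc25a31 (2.20) among them, and 2 lower, Tex101 (-1.40) among them. Without library 1 the change of Gdf7 was 4.97. Counts adjusted over the list alone were the same for every list in this contrast.

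Outside the lists, the largest rises by fitted value were at genes with no fragment in 3T3-like cells. Pcdha12, a clustered protocadherin, had 330 fragments in mESC-like cells, 0 in 3T3-like and 11 in Oli-neu-like cells, so it was at least 34.5-fold higher than in 3T3-like cells and 26.4-fold higher (14.5 to 53.3) than in Oli-neu-like cells. Pdzrn4, Lzts3, Tmod1, Npm3, Pcdhb11, Aff2, Fastkd5, H2-T-ps and Lrp1b completed the 10, with at least 5.85-fold (Fastkd5) to at least 31.3-fold (Tmod1) more than in 3T3-like cells. Lzts3 and Fastkd5 are neighbours on chromosome 2. The largest falls by fitted value were B4galnt3 (1 fragment in mESC-like against 46 in 3T3-like cells, 146.8-fold lower, 25.1 to 5923), Gm17359, Csta3, Krtap31-1, Zfp109, Pgbd1, Clec2h, Golm2, Clec2f and Iqgap3, all with 0 to 2 fragments in mESC-like cells. Without library 1 or library 2, with 1 added to each CPM value, the fitted log2 change of Pcdha12 went from 7.30 to 5.40 and 5.57, that of Pdzrn4 from 7.32 to 5.52 and 4.87, and that of Clec2h from -4.76 to -3.85 and -3.37.

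With edgeR, 7576 of 9898 tested genes differed in mESC-like cells, 4189 higher and 3387 lower, and 292 of them had no fragment in a class. The higher share was 55.3% with TMM and 65.7% with scaling by total fragments, which moved the median log2 fold change of all genes from 0.22 to 0.73. Camera set 12 of the 14 lists above other genes, with adjusted p = 1.45e-12 for neural patterning, 4.55e-07 for HoxA and 2.22e-06 for HoxD at the preset correlation. With an estimated correlation none held (adjusted p = 0.273 for each of the 12), and fry, which does not compare a list with other genes, gave adjusted p = 0.00200 to 0.00201 for them. Without the deepest 1% of cells, an alternative chosen after the data were seen, the medians of HoxA and HoxD rose to 5.02 and 4.87.

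**Figure D3:**
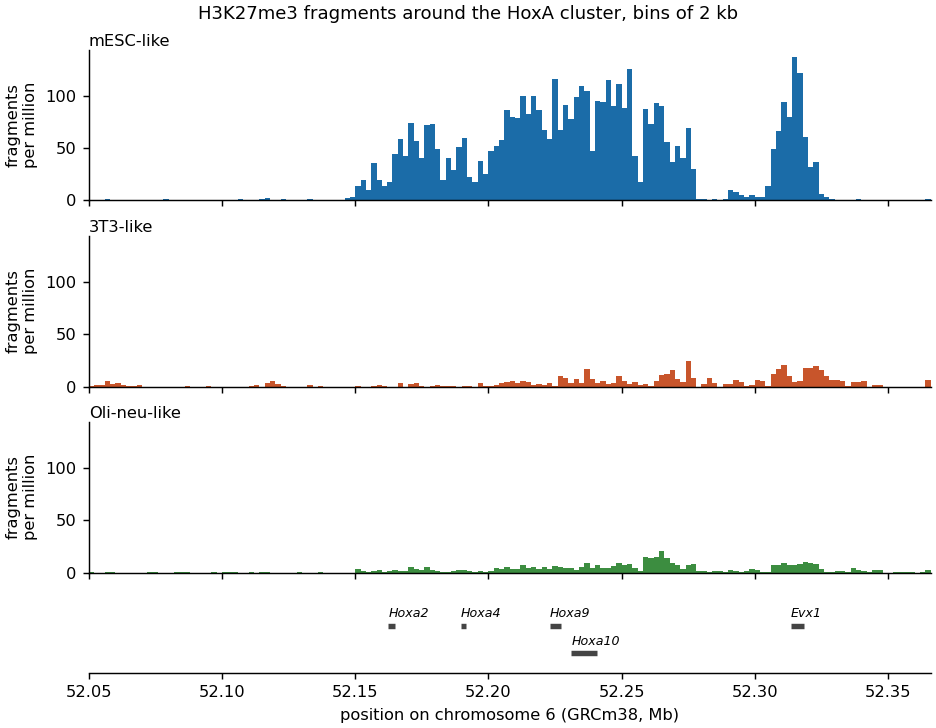
H3K27me3 around the HoxA cluster on chromosome 6 in bins of 2 kb, as CPM of each class (vertical axis, same scale in all 3 panels) by position in Mb, with both libraries pooled. Grey bars are Hoxa2, Hoxa4, Hoxa9, Hoxa10 and Evx1. Mean levels per gene over the cluster were 471.2 in mESC-like, 24.2 in 3T3-like and 30.8 in Oli-neu-like cells.

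3T3-like cells against the other classes: the Hox clusters and the neural and mesodermal regulators were below the mean of the other classes in fibroblast-like cells. All 11 HoxA genes fell (median log2 fold change -2.29), all 10 HoxB (-1.62), all 9 HoxC (-1.74) and 8 of 9 HoxD (-2.24, and all 9 when adjusted over the list alone). Neuronal differentiation factors fell in 25 of 28 cases (-1.92), neural patterning factors in 21 of 26, mesoderm and muscle factors in 19 of 22, and Wnt and BMP ligands in 18 of 21. The mean of the other classes is lifted by mESC-like cells at these genes: the median HoxA gene stood at 24.9 CPM in 3T3-like, 35.8 in Oli-neu-like and 384.4 in mESC-like cells. Neural patterning factors (45.1 against 37.5) and mesoderm and muscle factors (34.1 against 33.2) were not lower in 3T3-like than in Oli-neu-like cells at the median gene.

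HoxC genes were lower in 3T3-like cells than in each of the other classes at the median gene, and Hoxc4 stood at 71.8 against 489.2 in mESC-like and 342.4 in Oli-neu-like cells (-2.52 ± 0.18) and Hoxc6 at 90.3 against 651.1 and 398.5 (-2.50 ± 0.17). Hoxd4 changed by -3.43, Hoxd8 by -2.75, Hoxa4 by -3.19, Hoxb2 by -2.10 and Hoxb5 by -1.86. Pax8, a factor of thyroid and kidney development, fell by 3.88 on the log2 scale, with 9.21 CPM against 180.9 and 103.2. Lhx2 had a log2 change of 0.14, and Dbx2 rose as the only neural patterning factor to do so. Among neuronal factors Dlx1 fell by 3.25 and Phox2a by 3.04, and among signals Wnt5a fell by 3.16 and Gdf6 by 2.80. Meox1 and Tbx4 were the mesoderm and muscle factors that rose, while Myf6 and Myf5, with no fragment in 3T3-like cells, had the largest fitted falls of their list. Myf6 was at least 5.01-fold lower than in mESC-like cells, and Myf5 did not pass with DESeq2. Without library 1 the changes were -3.83 for Hoxd8, -4.67 for Dlx1, -2.25 for Phox2a, -2.84 for Myf6 (fitted at -6.13) and -1.92 for Myf5 (fitted at -5.28). Without library 2 they were -2.50 for Dlx1, -3.12 for Myf6 and -2.53 for Myf5.

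Endoderm factors fell in 8 of 12 cases, Gata6 (-2.98) and Sox7 (-2.79) among them, and Hnf4a and Pdx1 rose. Imprinted genes fell in 8 of 14, Igf2 (-2.99) and Magel2 (-2.17) among them, and Sgce rose. Blood and immune factors fell in 4 of 9, Lyl1 (-3.01) and Gata2 (-2.54) among them, and rose in 2. Cell cycle inhibitors fell in 4 of 7, Cdkn2a (-3.00) and Cdkn2c (-2.87) among them, and Cdkn2d rose (2.15). Astrocyte and radial glia genes fell in 4 of 8, Slc1a3 (-2.88) and Sox9 (-2.28) among them, and rose in 2. Germline genes fell in 3 of 9, Dazl (-2.98) and Sycp1 (-2.60) among them, and rose in 3. Without library 1 the changes were -5.61 for Magel2, -3.90 for Slc1a3, -3.68 for Cdkn2a, -3.50 for Sox7, -3.37 for Gata2 and -1.83 for Sycp1. Without library 2 they were -1.44 for Magel2, -1.81 for Slc1a3 and 1.32 for Cdkn2d.

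The 3 largest rises by fitted value were H2bc15, H2ac15 and H4c12, histone genes at 1 locus on chromosome 13 (21750145 to 21754553) that share fragments, with 20 to 22 fragments in 3T3-like cells and 0 in the other classes. H2bc15 was at least 23.4-fold higher than in mESC-like cells and at least 20.6-fold higher than in Oli-neu-like cells, and none of the 3 passed with DESeq2. The others of the 10 were Angptl1 (46 fragments against 2 and 2), Gpr171 (27 against 1 and 1), Tshb (56 against 11 and 1), Apoc1, Abca8a, Gm17359 and 1700010I14Rik. The largest falls by fitted value, all with no fragment in 3T3-like cells and so without a measured size, were Xlr, Tnfrsf1b, Aqp1, Ccdc9b, Tmod1, Gpat3, Lrig1, R3hdm4, Npm3 and Gprc5a. The water channel gene Aqp1 was at least 11.4-fold lower than in Oli-neu-like and at least 6.58-fold lower than in mESC-like cells, and Ccdc9b at least 24.7-fold lower than in mESC-like cells. Npm3 did not pass with windows of 2.5 kb. Without library 1 or library 2, with 1 added to each CPM value, the fitted log2 change of H2bc15 went from 7.72 to 4.77 and 4.08, that of Angptl1 from 5.90 to 4.75 and 4.75, and that of Aqp1 from -7.95 to -4.41 and -4.79.

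With edgeR, 6023 of 9898 genes differed in 3T3-like cells, 2745 higher and 3278 lower, and 414 of them had no fragment in a class. The higher share was 45.6% with TMM and 37.3% with scaling by total fragments, and after thinning to equal fragments the balance turned, with 2033 higher and 1965 lower of 3998. Camera set 10 lists below other genes at the preset correlation, with adjusted p = 1.01e-09 for neuronal differentiation factors, 7.77e-08 for HoxC, 0.0136 for endoderm factors and 0.0281 for imprinted genes. It did not call the astrocyte, blood, cell cycle (adjusted p = 0.0759) and germline lists. With an estimated correlation none held (adjusted p = 0.158 to 0.244 for the 10), and fry gave adjusted p = 0.00301 to 0.0176 for them. Without library 1 the HoxD median was -3.02.

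Oli-neu-like cells against the other classes: the neural patterning factors were below the mean of the other classes in the mark, and receptor genes of smell and pheromone sensing, such as Olfr979 and Vmn1r41, were among the largest rises. Neural patterning factors fell in 25 of 26 cases (median log2 fold change -1.72), neuronal differentiation factors in 22 of 28 (-1.28) and mesoderm and muscle factors in 19 of 22 (-1.64). HoxA (9 of 11, -1.66) and HoxD (9 of 9, -1.62) fell against the mean of the other classes, although their median gene stood higher than in 3T3-like cells, at 35.8 against 24.9 CPM and 32.9 against 24.9 CPM. The pooled medians of neuronal differentiation factors, endoderm factors (52.6 against 33.6) and Wnt and BMP ligands (59.5 against 36.8) also stood higher than in 3T3-like cells, all far below mESC-like cells. At HoxA this order varied with depth, in 10 equal groups of cells per class from shallow to deep. In cells of middle depth (groups 5 and 6) the HoxA region held 74.3 CPM in Oli-neu-like and 108.6 in 3T3-like cells. Oli-neu-like cells were also lower in groups 1 and 2, and higher in groups 3, 4, 7, 8, 9 and 10. The counting intervals of the 2 classes overlapped in all groups except group 10. There they were 459.9 to 538.7 in Oli-neu-like and 309.9 to 432.1 in 3T3-like cells. The other lists were not split by depth. Neural patterning factors (37.5 against 45.1) and mesoderm and muscle factors (33.2 against 34.1) stood near 3T3-like cells at the median gene, with mESC-like cells at 404.9 and 275.3. HoxC, by contrast, kept a middle level of 277.6 at the median gene, between 90.3 in 3T3-like and 489.2 in mESC-like cells, and olfactory receptor genes supplied 5 of the 10 largest rises.

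Neurog1, a factor that starts neuronal differentiation, stood at 25.6 in Oli-neu-like cells against 389.9 in mESC-like and 93.9 in 3T3-like cells (-2.89 ± 0.20), and Neurod1 fell by 2.89 too. Lhx2 fell by 2.74 and Dbx2 by 2.60, both below 3T3-like as well as mESC-like cells, and Pax8 rose (103.2 CPM against 9.21 in 3T3-like cells) while staying below mESC-like cells (180.9). Tbx4 changed by -2.81 and Meox1 by -2.66. In the Hox clusters Hoxa10 changed by -2.02, Hoxa9 by -1.80, Hoxd1 by -2.51 and Hoxd10 by -1.84. Hoxc4 (0.87) and Hoxc6 (0.72) rose with 2 other HoxC genes and none fell, but Hoxc4 and Hoxc6 did not pass with totals per chromosome, and the median of the list (0.14) turned to -0.10 with scaling by total fragments. HoxB had 2 genes higher and 3 lower, with Hoxb3 at -0.63 and Hoxb4 at -0.39, and neither passed with windows of 2.5 kb. Without library 1 the change of Hoxd10 was -1.22.

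Wnt and BMP ligands fell in 15 of 21 cases, Bmp7 (36.1 CPM against 169.1 and 124.3) and Wnt2 (-1.92) among them, endoderm factors in 8 of 12, Gsc (-2.24) and Pdx1 (-2.22) among them, and blood and immune factors in 6 of 9, Tal1 (-2.27) and Cebpa (-1.86) among them. Cell cycle inhibitors fell in 4 of 7, Cdkn2b (-1.82) and Cdkn2c (-1.58) among them, and both calls ended under at least 1 alternative. Imprinted genes fell in 6 of 14, Phlda2 (-2.46) and Slc22a18 (-1.26) among them, and rose in 2. Astrocyte and radial glia genes went both ways, 4 higher and 4 lower, with Hes5 at -2.30 and Fabp7 at -2.24. Of the germline genes 3 of 9 rose, Dazl, an RNA-binding protein of germ cells, to 97.9 CPM against 13.9 in mESC-like and 4.61 in 3T3-like cells, and 2 fell, Slc25a31 by 2.49. Without library 2 the change of Fabp7 was -1.59. Adjusted over the list alone, the falls were 10 in HoxA, 23 in neuronal differentiation factors, 17 in Wnt and BMP ligands and 3 in germline genes, and the rises were 1 in HoxB and 1 in mesoderm and muscle factors, with the other counts the same.

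The largest rises by fitted value were the olfactory receptor genes Olfr979, Olfr169 and Olfr1289, of which Olfr979 and Olfr1289 had 36 and 26 fragments in Oli-neu-like cells and 0 in the other classes, then Cdkl2, Vmn1r41, Chil4, Mup5, Olfr722, Olfr231 and Krtap4-6. Olfr979 was at least 13.7-fold higher than in mESC-like and at least 4.28-fold higher than in 3T3-like cells, and Chil4, a chitinase-like protein gene, 9.59-fold higher (5.94 to 16.3) than in mESC-like and at least 19.0-fold higher than in 3T3-like cells. The largest falls by fitted value, all with no fragment in Oli-neu-like cells, were Gm15266, Ttpa, Jakmip2, Pde7b, Ripply1, Trim44, Gm614, Il2rg, 1110004F10Rik and Gm52229, with 10 to 20 fragments each in 3T3-like cells. Jakmip2 was at least 12.1-fold lower than in 3T3-like and at least 4.98-fold lower than in mESC-like cells. Gm614 and Il2rg are neighbours that share fragments. Without library 1 or library 2, with 1 added to each CPM value, the fitted log2 change of Olfr979 went from 6.92 to 3.72 and 3.65, that of Chil4 from 6.15 to 4.06 and 4.65, and that of Jakmip2 from -6.29 to -2.93 and -3.25.

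With edgeR, 6310 of 9898 genes differed in Oli-neu-like cells, 3381 higher and 2929 lower, and 244 of them had no fragment in a class. The balance turned with scaling by total fragments (2942 higher, 3402 lower) and with totals per chromosome (2914 and 3348). The count was 3455 after thinning to equal fragments and 4203 with windows of 2.5 kb. Camera set 8 lists below other genes at the preset correlation, with adjusted p = 5.10e-11 for neural patterning factors, 1.67e-06 for mesoderm and muscle factors and 0.000508 for HoxA. None held with an estimated correlation (adjusted p = 0.480 to 0.530 for the 8), and fry gave adjusted p = 0.0506 to 0.104 for them, so none passed. The HoxD median was -0.99 without library 1 and -2.46 without the deepest 1% of cells, an alternative chosen after the data were seen.

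Against depth, the classes drew nearer to each other in their deepest cells. In mESC-like cells the HoxA region (chromosome 6, 52150367 to 52265880) held 4767 CPM in the cells of middle depth and 2394 in the deepest 10% of cells of the class. It held 108.6 and 367.2 in 3T3-like cells, and 74.3 and 498.1 in Oli-neu-like cells. Ranked over all cells of a library instead, the deepest 10% of cells of each library held 40.3% of the fragments of Oli-neu-like cells, 31.5% of mESC-like and 25.1% of 3T3-like cells.

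**Figure D4:**
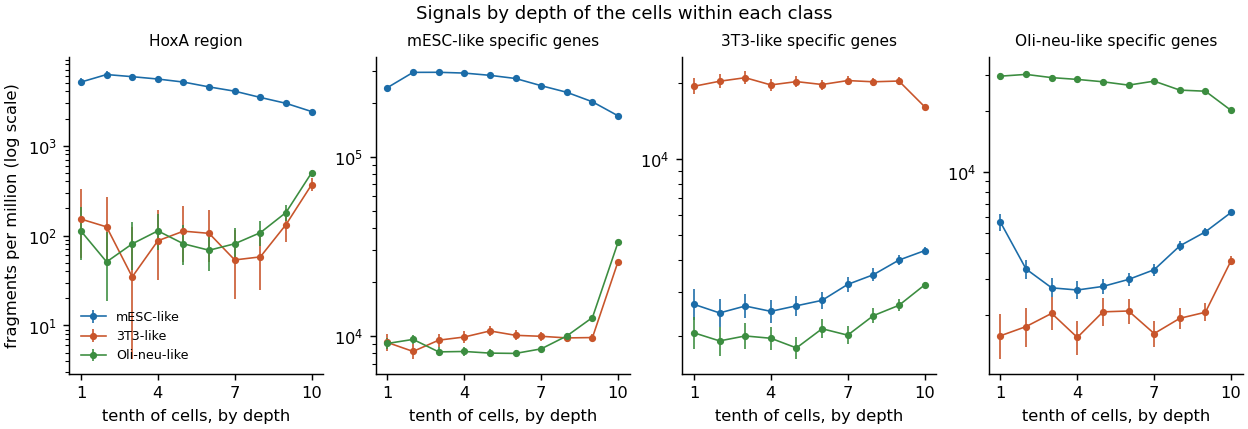
CPM (log scale) in the HoxA region and at the genes specific to each class, in 10 equal groups of cells ordered by depth within each class, from shallow to deep. Points are pooled over both libraries, bars are exact 95% counting intervals, and specific genes passed the test with at least 4-fold more than in each other class (1777 genes for mESC-like, 533 for 3T3-like, 774 for Oli-neu-like). In all 3 classes the genes specific to the other classes are higher in the deepest group than in the middle groups.

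The 2 libraries were compared as values only, with 1 library on each side. Library 2 was read more deeply per fragment, with 35.3 read pairs per fragment in cells against 24.3 in library 1. Its median fragment was 370 bp against 365 bp, and 10.9% of its fragments were under 120 bp against 9.92%. Unnamed cells carried that last difference (46.6% against 37.9%), as each named class had a lower share under 120 bp in library 2: 9.54% against 10.4% in mESC-like, 5.83% against 6.16% in 3T3-like and 8.14% against 8.57% in Oli-neu-like cells. By class, the median fragment was 374 bp in mESC-like, 393 bp in 3T3-like, 372 bp in Oli-neu-like and 153 bp in unnamed cells, where 43.2% of fragments were under 120 bp against 6.02 to 10.0% in the named classes.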

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

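All tests in this part were chosen only after the result was seen, except the count of matches with exchanged barcodes. No biological explanation was tested for any of the results here, since the design gives none.

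Unnamed cells stood apart at housekeeping genes, which the comparisons between the lines did not use: 47.0 CPM per gene against 1.30 in mESC-like, 1.13 in 3T3-like and 1.15 in Oli-neu-like cells. Barcodes with cells of more than one line cannot account for the group as a whole, because a mixture of the 3 classes cannot exceed the highest of them and the ratio to it was 36.1 (95% counting interval 26.8 to 49.3). Shallow cells of the 3 lines cannot either, because the level was 45.3 times (21.7 to 114) that of named cells no deeper than the median unnamed cell. Both tests pool all unnamed fragments, of which 11 of the 686 cells held 26.4%. Neither test excludes such barcodes or cells as a part of the group. Reads swapped in from another library of the same run remain open as a hypothesis: the median unnamed barcode had 1.03 read pairs per fragment against 20.5 to 22.4 in the named classes, and 225 barcodes were unnamed in both libraries where chance gives 1.11. They do not account for all of the unnamed fragments: 87.3% of the barcodes had under 2 read pairs per fragment, but the mean over all unnamed fragments was 41.4 (80.5 in library 1 and 15.7 in library 2).

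The 2 libraries shared 689788 fragments with the same ends and the same barcode, 14.7% of library 1 and 16.9% of library 2. The main comparisons kept these fragments and made no use of the sharing. Chance coincidence is excluded, with 0 matches (0%) after barcodes were exchanged at random, and so are the same cells sequenced in both libraries, since 0.591% of shared fragments had read pairs within 2-fold. Index swapping between the 2 libraries fits: 30.1% of library 1 fragments with 50 or more read pairs, but 3.28% of those with 10 or more but under 20, were found in library 2 with under 10 read pairs, a ratio of 9.19 (9.08 to 9.29). Earlier forms of this test were replaced after their values were seen: one also counted the copies that library 1 had received (1.51), and one asked for fewer read pairs in library 2 than in library 1 (47.8), which fragments with few read pairs can hardly meet. Of the 751 barcodes over the cell minimum in both libraries, 471 were over 90% copies in one of them and 222 were under 10% copies in each.

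Barcodes under the cell minimum, which no comparison used, held 6183 CPM at the 4 Hox clusters, against 14620 in mESC-like, 1586 in 3T3-like, 3466 in Oli-neu-like and 2345 in unnamed cells, while 43.1% of their fragments were copies of fragments in the other library and the housekeeping genes together took 230.5 CPM there (15.6 to 19.2 in the named classes and 700.6 in unnamed cells).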

How the results depend on the processing

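The alternatives without copies between libraries, with at least 5 read pairs per fragment, at a clustering resolution of 0.4, without the deepest 1% or 10% of cells, and with windows of all 3 classes were chosen only after the data were seen, and the others were planned. The cause of a move was not tested unless the construction of the alternative is named. No paired analysis was possible by labelled replicate number, because the samples that share such numbers are brain samples without data here. The main fit pairs the classes by library through the library term, and without that term 7691, 6134 and 6425 genes differed in mESC-like, 3T3-like and Oli-neu-like cells.

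No gene list or named gene that was called changed direction. The count of genes differing in mESC-like cells stayed at 5122 to 7964. In 3T3-like cells it was 3998 with equal fragments per class and library, and 4270 to 6733 otherwise. In Oli-neu-like cells it was 3455 with equal fragments and 4203 with windows of 2.5 kb, and 4553 to 7442 otherwise. Equal fragments and windows of 2.5 kb left 6396 and 7580 genes to test. Leaving out 1 library kept the direction of 7555 to 7569 of 7576 genes in mESC-like, 6011 to 6019 of 6023 in 3T3-like and 6280 to 6305 of 6310 in Oli-neu-like cells. With an estimated correlation, gene lists called by camera went from 30 to 0. That form rests on 2 residual degrees of freedom, so the loss does not show that correlation explains the calls. Imprinted genes in mESC-like cells had an estimated correlation of -0.0094, below the preset 0.01. Their unadjusted p with camera still went from 0.0068 to 0.103. Of 756 list medians under alternatives, 311 moved by more than the spread between libraries. Of 2485 named-gene values under alternatives, 2461 kept their side of the threshold where tested and 24 lost it. Of the 144 named fold changes, 76 moved by over 1.5-fold without a library, 137 moved by as much under at least 1 alternative of any kind, and 0 changed direction without a library. Those near 0 shrink by construction, since 1 is added to each CPM value. Scaling by total fragments moved the median log2 change of all genes from -0.37 to -0.65 in 3T3-like and from 0.01 to -0.23 in Oli-neu-like cells.

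The number of cells ran from 6956 at a minimum of 376 fragments to 13070 at 94. It was 9613 without copies between libraries and 9025 with at least 5 read pairs per fragment. At 376 the shares were 37.1% mESC-like, 16.9% 3T3-like, 42.5% Oli-neu-like and 3.55% unnamed, and at 94 mESC-like cells made 22.8%, Oli-neu-like 36.5% and unnamed 21.8%. Even-numbered autosomes alone named 4624 cells mESC-like at 94 and left 1138 unnamed. The mESC-like share, nearly equal in the libraries, was 34.9% with 5 kb bins, 35.0% without cells of differing classes and 35.1% without copies. K-means with 3 clusters gave 31.3% mESC-like, 28.7% 3T3-like and 0% unnamed. At least 5 read pairs per fragment gave 37.7% mESC-like, 20.8% 3T3-like, 41.5% Oli-neu-like and 0% unnamed. A resolution of 0.4 gave 18.8%, 24.9% and 17.0% for mESC-like, 3T3-like and unnamed cells. The agreement of the autosome sets was 86.6% at a minimum of 94 and 94.0% with 5 kb bins.

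Concentration with 50 kb windows was 54.7% in mESC-like, 42.0% in 3T3-like, 42.0% in Oli-neu-like and 23.5% in unnamed cells. With windows of all 3 classes it was 59.3%, 34.9%, 43.3% and 20.2%, with 5 kb windows 49.3% in 3T3-like and 49.0% in Oli-neu-like cells, and after thinning 46.5% in Oli-neu-like cells against 47.9% in 3T3-like cells. Without 1 library it ran from 62.3 to 64.8%, 47.8 to 48.7%, 47.2 to 48.0% and 27.8 to 33.9%. Without the highest windows, chromosome 3 took 6.48% and chromosome 14 3.5% in 3T3-like cells, chromosome 15 4.78% and chromosome X 2.27% in Oli-neu-like cells, and chromosome X 3.64% and chromosome 15 3.90% in mESC-like cells. In library 2, thinned cells gave 26.3 read pairs per fragment, a median length of 366 bp and 12.3% of fragments under 120 bp. In library 1 they gave 17.9 read pairs, 364 bp and 10.2%. Depth limits how many genes can be tested, 6396 with equal fragments against 9898. In simulated data, where far fewer genes were changed than were called here, 2-fold falls were recovered in 28 to 54% of cases.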

Other observations

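All tests in this part were chosen only after the result was seen: the families were picked once the named genes were known, as the 62 sets of symbols with the same leading letters and at least 15 tested genes. Only members that passed the filter on low counts are counted. A gene with few fragments in the other classes can pass through a single class. The share of a family that rose in such a class, its median change and its camera p-value are therefore partly set by the filter. The share is not one of the whole family, and the p-value is not independent support for a rise.

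In Oli-neu-like cells H3K27me3 was above the mean of the other classes over the tested genes of many families, those of olfactory receptors and keratins among them. A rise here is relative to those classes: the median tested olfactory receptor gene lay below the median HoxA gene of Oli-neu-like cells (35.8 CPM). Of 287 tested olfactory receptor genes (Olfr), 247 rose and 9 fell, with a median log2 fold change of 2.49 (2.39 with genes at 0 in a class set to their bound) and a median level of 14.8 CPM against 2.31 in mESC-like and 3.68 in 3T3-like cells. Vomeronasal receptor genes (Vmn), which serve pheromone sensing, rose in 35 of 37 cases (3.21, bound 2.92), trace amine receptor genes (Taar) in 15 of 15 (2.22), and keratin genes (Krt) in 52 of 53 (1.75, at 92.7 CPM against 13.6 and 34.1). Serpinb protease inhibitor genes rose in 20 of 20 cases (2.82, bound 2.43), keratin-associated protein genes (Krtap) in 24 of 30, beta-defensin genes (Defb) in 20 of 22 (2.02, bound 1.85) and carboxylesterase genes (Ces) in 17 of 19 (1.84). Camera, adjusted over the 62 families, set them above other genes at the preset correlation, with adjusted p = 1.80e-18 for Olfr, 2.73e-17 for Krt, 3.63e-09 for Vmn, 4.88e-07 for Krtap, 2.37e-06 for Serpinb, 9.41e-06 for Taar, 2.86e-05 for Defb and 4.95e-05 for Ces. The families Wfdc, Ms, Cyp, Ugt, Ly, Cd, Clec, Tmprss, BC and Mmp were also set above other genes, with adjusted p from 4.95e-05 (Wfdc) to 0.0420 (Mmp). None of all these held with an estimated correlation (adjusted p = 0.494 to 0.621), and neighbouring family members share windows. Some of these families were low in mESC-like cells, where 45 Krt genes fell and 1 rose, 143 Olfr genes fell and 4 rose, and all 15 Taar genes fell (-2.93), with adjusted p = 3.50e-12, 1.15e-07 and 6.02e-05, or 0.386 for each with an estimated correlation. Of the Vmn genes 21 of 37 and of the Serpinb genes 7 of 20 fell in mESC-like cells (adjusted p = 0.00485 and 0.0450, or 0.386 and 0.418 with an estimated correlation), and none rose. In 3T3-like cells 76 Olfr genes fell and 62 rose while 9 Serpinb genes fell and 1 rose.

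In mESC-like cells the 22 tested genes of the beta protocadherin cluster (Pcdhb), cell adhesion genes of neurons on chromosome 18, all rose, with a median log2 fold change of 4.03 (bound 3.99) and a median level of 54.3 CPM against 2.76 in 3T3-like and 4.93 in Oli-neu-like cells. Sox transcription factor genes rose in 15 of 17 cases (3.19, bound 2.98) and collagen genes (Col) in 29 of 41. Adjusted p with camera was 5.72e-07 for Pcdhb, 1.35e-04 for Sox and 0.00376 for Col, and 0.418, 0.418 and 0.386 with an estimated correlation. In 3T3-like cells 18 Pcdhb genes fell and 0 rose (-2.38, bound -2.34, adjusted p = 0.00148, and 0.698 with an estimated correlation), and serine protease genes (Prss) rose in 16 of 28 cases and fell in 5 (adjusted p = 0.00422, and 0.698 with an estimated correlation). Without the deepest 10% of cells the medians in mESC-like cells were 6.70 for Pcdhb and 4.44 for Sox, that of Pcdhb in 3T3-like cells was -3.80, and those in Oli-neu-like cells were 4.27 for the 19 Vmn genes still tested and 2.57 for Ces. These are fitted values without a bound. With all cells the median Pcdhb gene already lay at the floor of 3 fragments (2.76 CPM) in 3T3-like cells, so 6.70 and -3.80 are not measured sizes.

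At a finer clustering, with a resolution of 0.4, 9 clusters formed: 606 of the unnamed cells took the name 3T3-like, and clusters of 872 and 850 cells, drawn mostly from mESC-like cells, had no line's markers low enough for a name.

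The deepest cells of each class carried less of the class's own signal and more of the others': the level at a class's specific genes was lower by 39.2% in mESC-like, 19.2% in 3T3-like and 26.1% in Oli-neu-like cells in the deepest 10% than at middle depth. More background spread evenly over the genome cannot alone account for the HoxA signal in deep 3T3-like and Oli-neu-like cells, which stood at 8.65 times (7.30 to 10.2) an even spread or higher. That test does not cover the fall of a class's own signal, so such background stays open as a part of that fall. Barcodes with cells of more than one line fit, as a hypothesis found and tested on the same data: all 6 ratios of other classes' genes, deepest over middle, exceeded 1, from 1.6 (1.5 to 1.72) to 4.17. The foreign share that those genes imply in the deepest cells, 23.8%, 12.2% and 16.1%, was smaller than these drops, and the shallowest 10% of mESC-like cells also stood high at Oli-neu-like specific genes (5673 CPM against 2872 at middle depth), which such barcodes do not account for, so both stay open. No biological explanation was tested, as the design gives none.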
